A study of Homo sapiens with 25 samples.

How the data were processed

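HCT116 cells with an empty or a FOXD2 lentiviral vector, under puromycin selection, were profiled for H3K4me1, H3K27ac, H3K4me3 and MLL4, and cells with a plasmid for FOXD2 carrying FLAG and 6xHis tags were profiled with antibodies to the tags. Per the labels' protocols, histone marks were precipitated from MNase-digested native chromatin, and MLL4 and the tags from formaldehyde-crosslinked, sonicated chromatin. The series has 25 libraries. Of these, 18 had a peak list and 7 inputs are not used here.

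The submitters' processing notes name cutadapt 3.4, Bowtie2 2.3.4.1, Picard, MACS2 2.2.7.1 and bedtools, and the build hg38. The authors deposited 1 narrowPeak list per library, so peaks were called per library and not on pooled samples. Column 7 of each deposited list holds the peak's fold enrichment as a ratio, and columns 8 and 9 hold its p-value and q-value as −log10. The largest q in the deposited lists was 0.01. Which library served as background for each list is not given in the sources used here, and neither is the read depth. Fold and score are the authors' own values for each peak and were used only to describe, rank or filter peaks within a list. Replicate numbers were taken from the labels, and in some files the peak names carry another number.

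Peaks on chromosomes 1 to 22 and X were kept, which left out between 1 and 35 peaks per list. For each mark, the lists were merged into regions (gap 0 bp), and a list held a region if at least 1 bp of a peak lay in it. A FOXD2-only region was held by both FOXD2 lists and neither control list, and a control-only region the reverse. A tag site was a merged region held by all 4 tag lists. Chance overlap was measured with 100 circular shifts of at least 1 Mb along each chromosome, with random seed 11. Shares carry 95% Wilson intervals, and odds ratios 95% Wald intervals on the log scale. These cover the counting of regions only. Region classes were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 3 marks for tag sites. Group means were compared by exact permutation tests, which cannot go below p = 0.333 with 2 libraries against 2.

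Regions were assigned to the nearest protein-coding gene of the RefSeq table of the same build, within 100 kb of the gene's span and at distance 0 inside it, with ties given to the nearer gene end. The planned rule used transcription start sites, but the table gives no strand, so gene spans and both gene ends took their place. Distal therefore means over 2 kb from both ends of every annotated gene. The 17 gene lists held 368 genes, all of which matched the table's 19974 protein-coding genes. They cover Wnt targets, epithelial junction and keratin genes, mesenchymal genes, intestinal identity, p53 targets, cell cycle, YAP and AP-1 targets, the TGF-beta and BMP pathway, the Notch pathway, interferon and inflammatory genes, H3K4 methyltransferase complexes, forkhead, HOX and ribosomal protein genes, and markers of blood, fibroblast and endothelial, and neural cells. Each list was tested per mark and direction against other genes with a region of the mark, by Fisher's exact test with adjustment over all 102 tests. The tag-site lists, 17 tests, were compared with all protein-coding genes. In a comparison chosen after seeing the data, each member was matched to the 200 genes nearest in number of regions, with 10000 draws.

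Named genes followed a rule set before the data were examined, as were the lists, most of the tests and most of the other settings below. The plan did not name the tests of gene lists at tag sites. Nor did it name those of control-only H3K27ac and control-only MLL4 at H3K4me1 regions. FOXD2 and the H3K4 methyltransferase genes came first. Then came the 10 regions of each class with the lowest sum of within-list ranks of −log10 q, the 5 genes with the most regions of each class, and up to 4 members of each gene list by the same rank.

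The alternatives were a stricter threshold (−log10 q of 5 or more), equal list lengths, an overlap of 50% of the shorter interval, a merging gap of 500 bp, each library left out in turn, other definitions of tag sites, regions of 300 to 2000 bp, distal regions, gene distances of 20 kb and 50 kb, and a replicate block. The motif search planned for the tag sites needs genome sequence and was not run. The steps were tested on simulated lists with 20000 regions planted as shared. These lists were smaller than the real H3K4me1 lists, drew all classes from the same range of widths and held more tag sites per region. The rates that follow therefore do not carry over to the real lists. Of 3000 planted FOXD2-only and 1000 planted control-only regions, 90.4% and 90.1% were found, against 90.2% by construction. A planted odds ratio of 2.06 gave a median of 2.07, and 96 of 100 draws passed 0.05, against 3 of 100 with no difference. A planted gene list was called in 87 of 100 draws. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.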

Results

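Chromatin immunoprecipitation with sequencing was used to map histone marks, the methyltransferase MLL4 and tagged FOXD2 in HCT116, an established human colorectal carcinoma line. FOXD2 is a forkhead transcription factor, and MLL4, encoded by KMT2D, places H3K4me1 at enhancers. Control cells carried an empty lentiviral vector and FOXD2 cells carried the FOXD2 coding sequence in that vector. H3K4me1, H3K27ac and MLL4 were each profiled in 2 control and 2 FOXD2 libraries, and H3K4me3 in 1 library per group. Tagged FOXD2 was mapped in cells given a FOXD2 plasmid, with 2 libraries for the 6xHis tag and 2 for the FLAG tag. Each of these 18 libraries had its own list of peaks, and the 7 input libraries are not used here. On chromosomes 1 to 22 and X, the H3K4me1 lists held 98480 ± 3852 peaks in control and 122390 ± 10602 in FOXD2 cells (SD, n = 2). The H3K27ac lists held 107914 ± 31228 and 113065 ± 39517 peaks, and the MLL4 lists 14808 ± 1750 and 13584 ± 12599 (SD, n = 2). The H3K4me3 lists held 24528 peaks in control and 22975 in FOXD2 cells. The tag lists held 48194 and 26942 peaks for 6xHis, and 38472 and 31424 for FLAG. Read depth per library is unknown, so the lists give the position of peaks and no limit of detection.

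The FOXD2 gene itself (hg38, chromosome 1, 47438044 to 47440691) held no peak in any of the 4 tag lists. H3K4me3, a mark of active promoters, lay over it in both H3K4me3 lists. It covered 900 bp of the gene in control and 1585 bp in FOXD2 cells. Reads from the FOXD2 coding sequence in the vector would map here too, so signal on the vector cannot be told apart from signal on the gene. H3K4me1 and H3K27ac peaks within the gene differed more between replicates than between groups, at 0.5 ± 0.7 H3K4me1 peaks in either group (SD, n = 2). A control-only H3K4me1 region, held by both control lists and neither FOXD2 list, lay beside the gene at 47427903 to 47428346. Peak lists give no expression level, so the amount of FOXD2 in these cells was not measured here.

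The first question was where the tag lists placed FOXD2. The series has a single input for the tag libraries and no tag library from cells without the tags. Agreement of the lists therefore cannot tell binding from a background that they share, which was not tested. The strongest sites, ranked by the authors' score over all 4 tag lists, lay in AP1S3, a clathrin adaptor subunit (chromosome 2, 223759585 to 223761457), and 8.2 kb from CPOX, a heme synthesis enzyme. The next ones lay in HSPH1, a heat shock protein with 2 sites among the top 10, and in COPS5, a COP9 signalosome subunit. The others of the top 10 lay in EIF4A2, MTHFD1L, TRA2B, OSR2 and HNRNPH1. EIF4A2 encodes a translation initiation helicase, and TRA2B and HNRNPH1 encode splicing factors. The sites at EIF4A2 and TRA2B were wide, at 9829 and 11207 bp, against a median of 1214 bp. The fold enrichment that the authors deposited for the AP1S3 site ran from 8.58 to 12.3 over the 4 lists. Sites and regions were counted at the nearest protein-coding gene within 100 kb, which they need not overlap. The genes with the most sites were HNRNPC, which binds pre-mRNA, with 18, GBF1 with 15, MED13 and VMP1 with 14 each, and MDM2, the p53 ubiquitin ligase, with 13.

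In all, 5399 sites were held by all 4 tag lists, which was 5.90% of the 91522 regions in any of them. After circular shifts of the lists along the chromosomes, the mean was 0.67 sites and the highest of 100 draws was 5. The lists shared 19.4% to 26.7% of their regions pair by pair, with the highest share between 6xHis replicate 1 and FLAG replicate 1. Of the 5399 sites, 4097 (75.9%) lay within a protein-coding gene and 3403 (63.0%) lay over 2 kb from both ends of every annotated gene. The sites fell at 2995 genes. Without 6xHis replicate 2, the shortest of these lists, 8578 sites were held by the other 3.

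The sites were then set against the chromatin lists. H3K4me3 was present in both of its lists at 1766 sites (32.7%, 95% Wilson interval 31.5 to 34.0), as at COPS5, MTHFD1L and OSR2. Another 1324 sites (24.5%) had no H3K4me3 and held H3K4me1 in all 4 lists, and 319 of these also held H3K27ac in all 4. No peak of these 3 histone marks lay at 1146 sites (21.2%, 95% Wilson interval 20.2 to 22.3), among them both top sites at HSPH1. MLL4 lay at 1667 sites (30.9%) in at least 1 list, as at AP1S3 and COPS5.

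H3K4me1 covered 66.7% ± 2.6 of the tag sites in control lists and 71.6% ± 0.52 in FOXD2 lists (SD, n = 2), a difference of 4.83 percentage points. H3K27ac covered 45.9% ± 1.3 and 50.6% ± 3.0 (SD, n = 2), a difference of 4.70 points. MLL4 covered 20.5% ± 1.1 and 13.1% ± 5.9 (SD, n = 2), a difference of -7.36 points. Each of these 3 differences gave an exact permutation p of 0.333, two-sided, which is the smallest that 2 against 2 allows. The differences kept their sign without any single library, but were 3.00 points for H3K4me1 without control replicate 2, 2.56 for H3K27ac without FOXD2 replicate 1, and -11.56 and -3.17 for MLL4 without FOXD2 replicate 1 and 2. At equal list length they were 2.23, 3.44 and -0.69 points. The longer H3K4me1 lists of FOXD2 cells also overlapped more sites by chance. Set against shifted sites, the H3K4me1 enrichment was 7.24 ± 0.33 times in control and 6.28 ± 0.35 times in FOXD2 lists (SD, n = 2), the opposite order. For H3K27ac and MLL4 the groups lay close together on this scale, with 5.39 ± 1.57 and 5.30 ± 1.89 times for H3K27ac and 18.8 ± 1.22 and 18.5 ± 11.7 times for MLL4 (SD, n = 2, exact permutation p = 1.0 for each). Within each of these 3 marks, this enrichment was lower the longer the list, from 7.48 times in the shortest H3K4me1 list to 6.04 in the longest. The scale therefore follows list length, and the order of the groups on it cannot be laid to FOXD2. Nothing in the labels says that replicates were separate cultures, so the permutation tests measure the spread between these libraries, which may be technical.

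**Figure D1:**
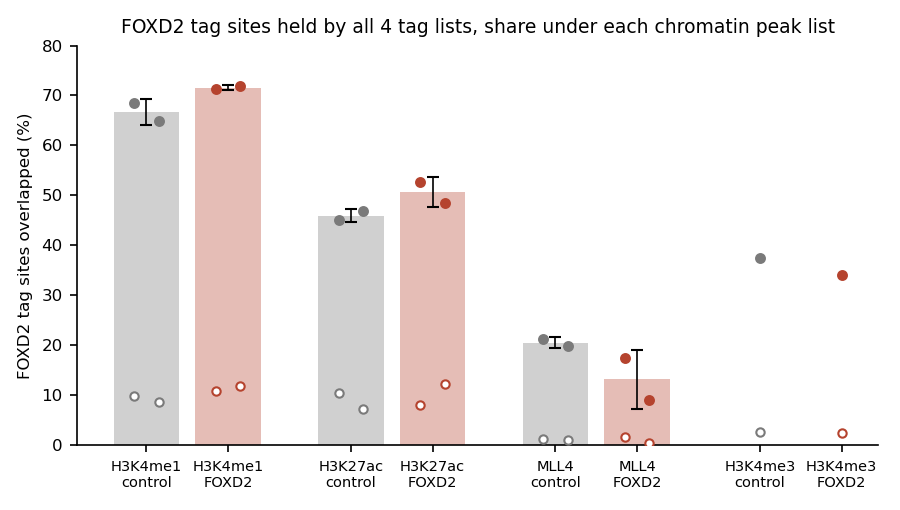
Share of the 5399 FOXD2 tag sites (percent, vertical axis) overlapped by each peak list, by mark and group. Filled points are libraries, bars their mean with SD (n = 2, and 1 library each for H3K4me3), and open points the share for shifted sites. H3K4me1 lists lie at 66.7% on average in control and 71.6% in FOXD2 cells.

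Tag sites lay near some of the fixed gene lists more often than near other genes. Of 20 epithelial junction and keratin genes, 10 had a site assigned to them, among them OCLN, CDH1, KRT20 and CLDN3, against 15.0% of other genes (Fisher's exact test, adjusted p = 0.0042 over 17 lists). Of 20 p53 targets, 9 held a site, including MDM2, TNFRSF10B, PLK3 and BBC3 (exact test, adjusted p = 0.011). Of 17 members of H3K4 methyltransferase complexes, 7 did, including KMT2A, PAXIP1, RBBP5 and DPY30 (exact test, adjusted p = 0.047). None of the 18 blood cell markers held a site (exact test, adjusted p = 0.23), and 3 of 16 fibroblast and endothelial and 1 of 16 neural markers did. With peaks of −log10 q of 5 or more, 0 of the 17 lists passed. When only genes with H3K4me3 in both lists were compared, a background chosen after seeing the data, 0 of the 17 lists passed by the exact test. The epithelial list then gave 9 of 19 against 21.0% (exact test, adjusted p = 0.16) and an unadjusted p of 0.0094, and the p53 list an unadjusted p of 0.023.

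The next question was where H3K4me1 differed between FOXD2 and control cells. The genes with the most FOXD2-only regions, held by both FOXD2 lists and neither control list, were LPP with 38, FGGY with 30, AKAP13 with 28, and JARID2 and PRKCE with 26 each. Counts per gene were not scaled to gene length or to all regions of the gene. In all, LPP had 123 H3K4me1 regions, FGGY 74, AKAP13 82, JARID2 80 and PRKCE 97. LPP spans 737.7 kb and JARID2 276.0 kb. LPP is a focal adhesion protein, JARID2 a cofactor of Polycomb repressive complex 2, and PRKCE a protein kinase C. Across LPP, H3K4me1 peaks covered 125.5 ± 17.2 kb in FOXD2 and 48.7 ± 4.1 kb in control lists (SD, n = 2). Across JARID2 they covered 125.0 ± 14.8 kb and 35.3 ± 6.1 kb (SD, n = 2). Here and below, coverage at genes picked by such counts comes from the same lists and is no separate support. The strongest FOXD2-only regions lay at TMEM154, at SPIDR, a DNA repair scaffold, at EIF4EBP2, a repressor of translation, and at MYZAP. SRGAP3, COLGALT2, PFKFB3, VKORC1L1, IP6K1 and CASP9 completed the top 10. The SPIDR region (chromosome 8, 47521456 to 47528207) carried deposited fold enrichments of 21.6 and 21.7 in the FOXD2 lists.

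Of KDM6A and the H3K4 methyltransferase genes, KDM6A, KMT2C and KMT2A had more H3K4me1 peaks in both FOXD2 lists than in either control list, while KMT2B, KMT2D, SETD1A and SETD1B did not. KDM6A, a histone H3K27 demethylase found in the MLL4 complex, held 36.0 ± 1.4 H3K4me1 peaks in FOXD2 and 14.0 ± 1.4 in control lists (SD, n = 2). These covered 38.4 ± 8.5 kb and 14.3 ± 1.2 kb of the gene (SD, n = 2). Its H3K27ac peaks numbered 3.5 ± 0.7 in FOXD2 and 5.0 ± 2.8 in control lists (SD, n = 2). In coverage the order was the opposite, with 4.9 ± 1.6 kb in FOXD2 and 3.4 ± 1.4 kb in control lists (SD, n = 2). KDM6A lies on X, where FOXD2-only regions made up 85.7% of the FOXD2-only and control-only H3K4me1 regions, the highest share of any chromosome. A difference along X cannot be told apart from one at KDM6A. KMT2C, the paralog of KMT2D, held 16.5 ± 4.9 and 5.0 ± 1.4 H3K4me1 peaks, and 4.0 ± 1.4 H3K27ac peaks against 0 in both control lists (SD, n = 2). KMT2A held 6.5 ± 0.7 and 3.0 ± 0.0 H3K4me1 peaks (SD, n = 2). KMT2D itself held 2.0 ± 0.0 and 2.5 ± 0.7 H3K4me1 peaks (SD, n = 2). KDM6A and KMT2C each had 11 FOXD2-only regions and no tag site of all 4 lists. The list as a whole had FOXD2-only H3K4me1 at 6 of 17 members, 35.3% against 41.8% of other genes (Fisher's exact test, adjusted p = 0.88). Per gene, 2 libraries against 2 cannot give an exact p under 0.333.

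Control-only H3K4me1 regions clustered at PCDH7, a protocadherin, with 47, at ZBTB20, a zinc finger repressor, with 32, and at MPP7, a scaffold of cell junctions, with 24. PPP3CA, the calcineurin catalytic subunit, held 20 and DCBLD2 19. In all, PCDH7 had 95 H3K4me1 regions over 426.4 kb, and ZBTB20 131 over 832.8 kb. Across PCDH7 (chromosome 4, 30720369 to 31146800), H3K4me1 covered 264.9 ± 11.9 kb in control and 50.9 ± 7.0 kb in FOXD2 lists (SD, n = 2). Across ZBTB20 it covered 148.3 ± 9.1 kb and 81.2 ± 0.4 kb (SD, n = 2). The strongest control-only regions with a gene in reach lay at PCDH7, IFNE, CPOX, PRKACB, TNS1, NCOA1, EPS8 and DST. Leaving out a library loosens both classes, since 1 list fewer must then hold or lack a region. With a merging gap of 500 bp, PCDH7 had 25 control-only H3K4me1 regions, and 5 of the 10 strongest control-only regions stayed in the class. Without control replicate 1 PCDH7 had 82 control-only regions, and without FOXD2 replicate 1 LPP had 76 FOXD2-only regions.

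**Figure D2:**
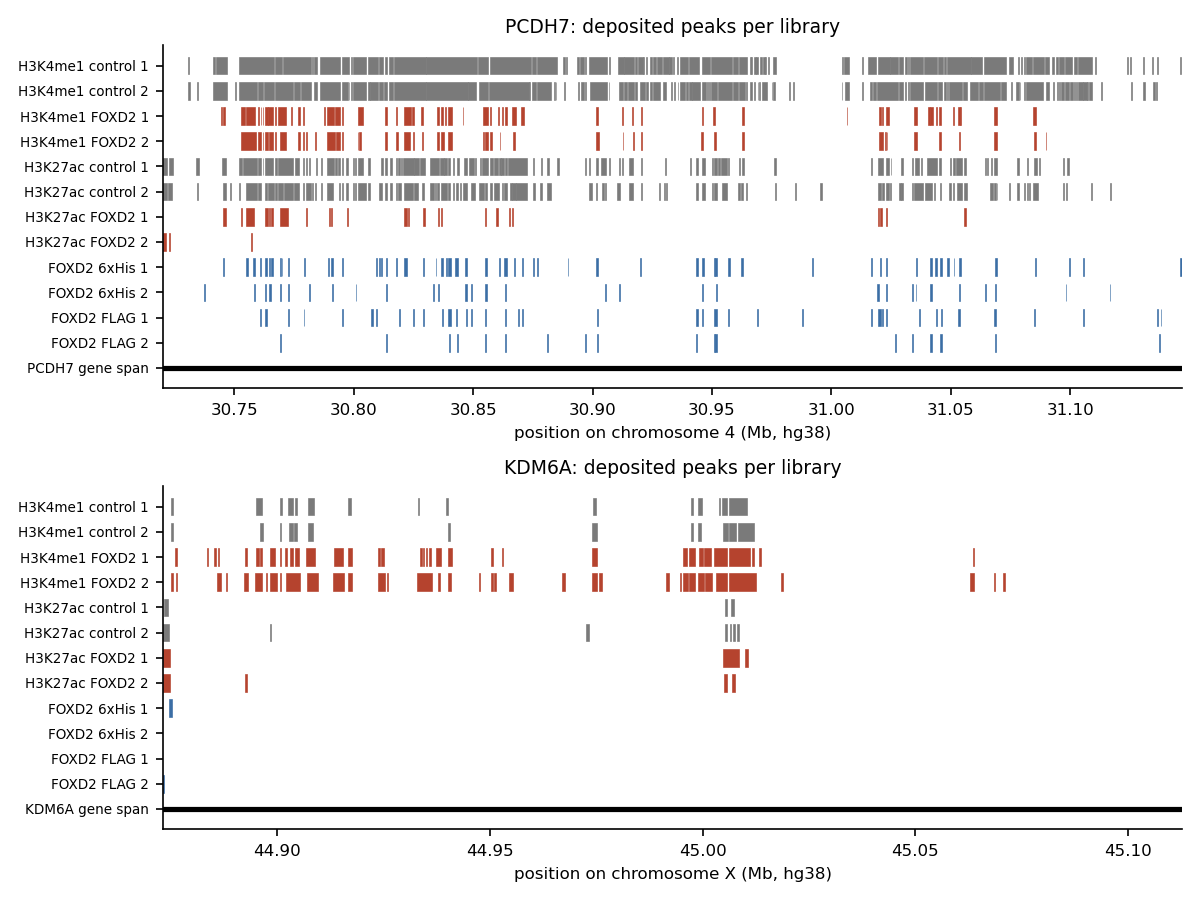
Deposited peaks of each library (rows, coloured by control, FOXD2 or tag) along PCDH7 and KDM6A, with position in Mb of hg38 on the horizontal axis. H3K4me1 covered 264.9 kb of PCDH7 in control and 50.9 kb in FOXD2 lists on average, and 14.3 kb and 38.4 kb of KDM6A. Both genes were picked for drawing after their values were seen. KDM6A lies on X, the chromosome with the highest FOXD2-only share for H3K4me1.

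Over the genome, 21471 of 150847 H3K4me1 regions were FOXD2-only, 6617 were control-only and 61998 were held by all 4 lists. The splits that pair a control with a FOXD2 library held 2711 and 2030 regions, and the 2 lists of a group shared 73.7% (control) and 70.1% (FOXD2) of their regions against 51.4% to 58.4% across groups. These counts were not tested, and the exact permutation test on 2 against 2 libraries cannot go below 0.333. FOXD2-only regions were 3.24 times as many as control-only ones. At equal list length, the ratio was 1.38 (13357 and 9693 regions), and without control replicate 2, it was 1.44 (24417 and 16900).

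Tag sites lay in 178 of the 21471 FOXD2-only H3K4me1 regions (0.83%, 95% Wilson interval 0.72 to 0.96) and in 29 of the 6617 control-only ones (0.44%, 0.31 to 0.63). The odds ratio was 1.90 (95% interval 1.28 to 2.81, Fisher's exact test, adjusted p = 1.09e-03 over 3 marks). FOXD2-only regions were wider, with a median of 935 bp against 700 bp, and wider regions overlap more sites by chance. Regions held by all 4 lists, with a median of 1855 bp, held a tag site in 5.69% of cases. Without FOXD2 replicate 1, the odds ratio was 1.28 and no longer passed. The splits that pair a control with a FOXD2 library gave odds ratios of 4.49 and 2.73. The first rests on 30 against 2 regions with a site (95% interval 1.07 to 18.8, exact test, p = 0.0198). The second rests on 20 against 5 (95% interval 1.02 to 7.31, exact test, p = 0.0404). Both values exceeded 1.90, but both intervals include it.

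**Figure D3:**
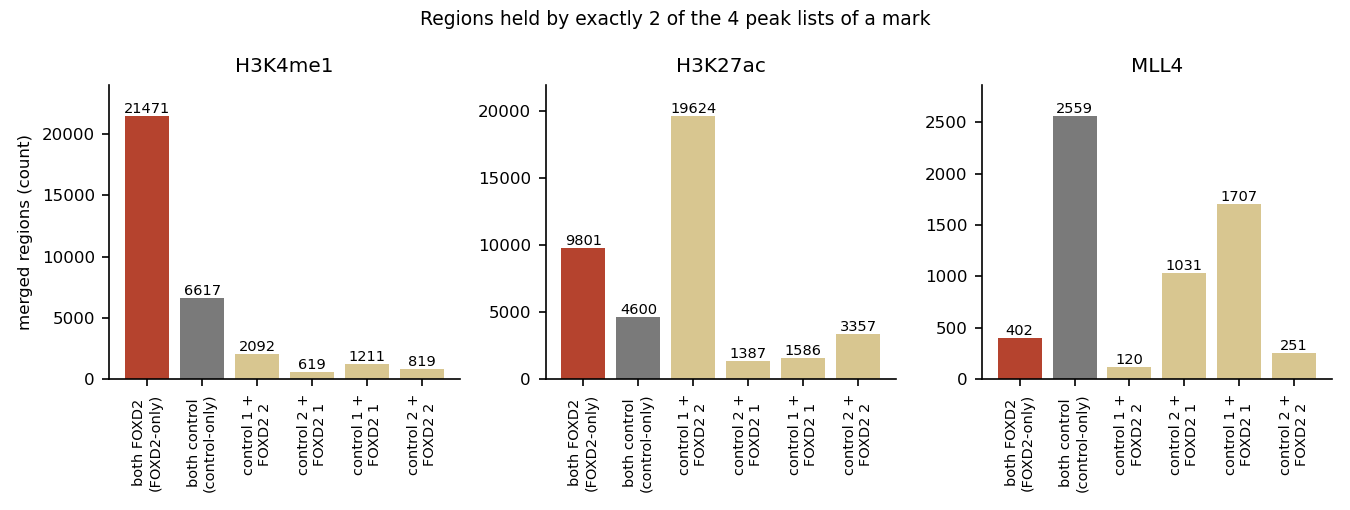
Number of merged regions held by exactly 2 of the 4 lists of a mark (vertical axis), for each pair of lists, with FOXD2-only in red, control-only in grey and mixed pairs in sand. For H3K27ac, control replicate 1 and FOXD2 replicate 2 alone shared 19624 regions, more than the 9801 FOXD2-only ones.

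H3K27ac, a mark of active enhancers and promoters, was compared in the same way. FOXD2-only regions were most numerous at AGAP1, an Arf GTPase-activating protein, with 21, and at SPIDR with 19. COBL, an actin nucleator, held 15, and TRAK1 and UBASH3B 14 each. In all, AGAP1 had 153 H3K27ac regions over 637.8 kb, and SPIDR 72 over 475.4 kb. Across SPIDR, H3K27ac covered 54.3 ± 1.9 kb in FOXD2 and 14.9 ± 2.0 kb in control lists (SD, n = 2). The strongest FOXD2-only region lay 28.2 kb from TMEM154 (chromosome 4, 152708182 to 152712489), within the strongest FOXD2-only H3K4me1 region. PADI2, SPINK9, HEBP2, IGFL4, KCNN3, FAM180A, TMBIM4, ST6GAL1 and REST, a repressor of neuronal genes, completed the top 10. At AGAP1, coverage was 87.2 ± 41.3 kb in FOXD2 and 35.2 ± 11.9 kb in control lists (SD, n = 2), and 76 regions were FOXD2-only without FOXD2 replicate 1.

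PCDH7 had 63 control-only H3K27ac regions, and 4 of the 10 strongest ones. H3K27ac covered 122.3 ± 3.3 kb of it in control and 11.2 ± 12.8 kb in FOXD2 lists (SD, n = 2). MPP7 had 20, HMGA2, a chromatin architectural protein, 13, and PHLDB2 11. Another 11 were nearest to BLID, a gene of 0.9 kb with no H3K27ac peak inside it in any list. HMGA2 was covered over 16.9 ± 2.4 kb in control and 7.0 ± 2.7 kb in FOXD2 lists (SD, n = 2). Others of the strongest control-only regions lay at WNT16, ABCC2 and PDE4B, a cAMP phosphodiesterase.

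Of 186853 H3K27ac regions, 9801 were FOXD2-only, 4600 control-only and 34631 in all 4 lists. Control replicate 1 and FOXD2 replicate 2, the longest lists, alone shared 19624 regions, and their 45.3% of shared regions exceeded the 40.6% and 38.7% within groups. FOXD2-only regions were 2.13 times as many as control-only ones, but 0.39 times without control replicate 2, 1.25 times without control replicate 1 and 7.75 times without FOXD2 replicate 1. Tag sites lay in 182 of the FOXD2-only (1.86%) and 69 of the control-only regions (1.5%) (odds ratio 1.24, 95% interval 0.94 to 1.64, exact test, adjusted p = 0.133). That odds ratio was 0.44 with peaks of −log10 q of 5 or more, 0.25 without FOXD2 replicate 1, 2.5 without FOXD2 replicate 2 and 4.60 without control replicate 2. With tag sites of at least 2 lists, it stayed above 1 and passed the threshold. It also did with the replicate block, which counts regions of either class under both replicate numbers, so that its p-value can be too small. The splits that pair a control with a FOXD2 library gave 0.04 (exact test, p = 1.95e-50) and 1.96 (exact test, p = 0.0283), both farther from 1.

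The next comparison asked whether H3K4me1 and H3K27ac differed at the same places. FOXD2-only H3K27ac lay at 1066 of the 21471 FOXD2-only H3K4me1 regions (4.96%), as at TMEM154, and at 40 of the 6617 control-only ones (0.60%). The odds ratio was 8.59 (95% interval 6.26 to 11.8, Fisher's exact test, p = 1.4e-78). Control-only H3K27ac lay at 39 FOXD2-only and 164 control-only H3K4me1 regions (odds ratio 0.07, exact test, p = 8.27e-67). The first of these odds ratios stayed above 1 without any single library and was 3.21 without H3K27ac control replicate 1, 3.41 without H3K27ac FOXD2 replicate 1 and 4.43 without H3K4me1 FOXD2 replicate 1. Regions are not independent replicates, and the test does not cover the spread between cultures. The series has 1 histone input per group, so the lists of both marks may share a background, and a difference between the inputs would make the classes of both marks coincide, which was not tested.

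MLL4 was compared last among the marks with replicates. FOXD2-only MLL4 regions were few, with 4 at CNIH3, an AMPA receptor auxiliary protein, 3 at SH3PXD2A and 2 each at AAK1, C11orf91 and GSE1, of which GSE1 also had 3 control-only ones. The strongest lay at ZCCHC4, CABP1, MTA3, COL4A2, KAZALD1, LMOD3, APIP, MACF1 and VDAC1. Control-only MLL4 regions were most numerous at CUX1, a homeobox factor, and SKAP1, with 6 each, at ST3GAL3 with 5, and at ABTB2 and ANO1 with 4. The strongest lay at PRKCZ, TEX36, TBC1D22A, ATP6V0D2, PRKCA, ASB4, NEK8, RGS9, NDRG1 and VWA7. Of control-only MLL4 regions, 74.3% overlapped H3K4me3, against 36.3% of FOXD2-only ones. CNIH3 had 2 FOXD2-only regions with peaks of −log10 q of 5 or more and also at equal list length, and CUX1 had 11 control-only regions without FOXD2 replicate 1.

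Of 35854 MLL4 regions, 402 were FOXD2-only, 2559 control-only and 2183 in all 4 lists. FOXD2 replicate 2 held only 4676 peaks. Without it, the order turned, with 13999 FOXD2-only and 3008 control-only regions, a ratio of 4.65 in place of 0.16, while the ratio was 0.09 and 0.08 without control replicate 1 and 2. At equal list length it was 0.59 (454 and 775 regions). Tag sites lay in 17 of the FOXD2-only (4.23%) and 241 of the control-only regions (9.42%), an odds ratio of 0.42 (95% interval 0.26 to 0.70, Fisher's exact test, adjusted p = 8.41e-04). It was 1.15 and 1.03 without control replicate 1 and 2, 0.15 without FOXD2 replicate 2, and 0.75, no longer past the threshold, at equal list length. The splits that pair a control with a FOXD2 library gave 3.28 (exact test, p = 1.06e-04), farther from 1, and 0.67 (exact test, p = 0.121).

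MLL4 was also sought at the H3K4me1 regions that differed. Regions with MLL4 in both FOXD2 lists lay at 16 of the 21471 FOXD2-only H3K4me1 regions and at 0 of the 6617 control-only ones (Fisher's exact test, p = 0.0185). In the other direction, control-only MLL4 lay at 0 FOXD2-only and 7 control-only H3K4me1 regions (exact test, p = 4.02e-05). Both comparisons rest on few regions and on a count of 0. The first no longer passed with peaks of −log10 q of 5 or more (exact test, p = 0.12). Nor did it at equal list length (exact test, p = 0.089) or with a gap of 500 bp (exact test, p = 0.051). With MLL4 in any of the 4 lists, a choice made after seeing the data, the counts were 279 and 232, an odds ratio of 0.36 (95% interval 0.30 to 0.43, exact test, p = 1.09e-27), the opposite direction. The first comparison has an odds ratio only with 0.5 added to each cell, which gave 10.2. It was 0.37 without MLL4 FOXD2 replicate 2, 51.7 without MLL4 FOXD2 replicate 1, 1.19 and past no threshold without H3K4me1 FOXD2 replicate 1, 24.3 without H3K4me1 control replicate 1 and 4.16 without H3K4me1 control replicate 2. Among single regions, the FOXD2-only H3K4me1 regions at TMEM154, MYZAP, COLGALT2 and IP6K1 overlapped an MLL4 peak of at least 1 list.

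H3K4me3 had 1 library per group and therefore no replicate check. Of 26149 regions, 20508 (78.4%) were in both lists, 1869 in the FOXD2 list alone and 3772 in the control list alone. At equal list length, these were 2198 and 2581. The regions of 1 list were narrow, with medians of 331 bp and 360 bp against 1653 bp for shared ones. They lay over 2 kb from gene ends in 76.4% and 75.2% of cases, against 31.8%. The strongest regions of the FOXD2 list alone lay at CPOX, TCP10L, PAX5, RLBP1 and PITPNC1, and those of the control list alone at SH3PXD2A, KDM8, TMEM218, CFAP65 and F2RL1. The genes with the most were DLGAP1, GNG7, SLC39A11 and TSPAN14 with 5 each in the FOXD2 list, and ADORA2B with 8 in the control list. Another 8 of the control list were nearest to IER3, which itself had 1 peak in each list.

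The fixed gene lists were tested for FOXD2-only or control-only regions of the 3 marks, in 102 tests, of which 4 passed an adjusted p of 0.05 and 17 an unadjusted one. Intestinal identity genes had control-only H3K27ac at 12 of 22 members (54.5% against 16.4% of other genes, exact test, adjusted p = 0.0051), including NEUROD1, GPA33, CDH17 and SPINK4. Genes of the TGF-beta and BMP pathway had control-only MLL4 at 11 of 21 members (52.4% against 17.0%, exact test, adjusted p = 0.012), including ID2, BMP7, SMAD3 and SMAD6. The same pathway had control-only H3K4me1 at 11 of 21 members, including SMAD6 and LTBP2 (52.4% against 21.5%, exact test, adjusted p = 0.047). More of its members, 15 of 21, had FOXD2-only H3K4me1 (71.4% against 41.8%, exact test, unadjusted p = 0.0073, adjusted p = 0.09), and 11 of 21 had FOXD2-only H3K27ac (52.4% against 29.1%, exact test, unadjusted p = 0.028, adjusted p = 0.21). Fibroblast and endothelial markers had FOXD2-only H3K4me1 at 13 of 15 members (86.7% against 41.8%, exact test, adjusted p = 0.026), among them COL6A3, ERG, VWF and PDGFRA. Blood cell markers had it at 5 of 16 and neural markers at 3 of 13 members (exact tests, adjusted p = 0.82 and 0.71). The fibroblast and endothelial, blood and neural lists were set in advance as markers of cell types that an HCT116 culture should not hold. A call on such a list is therefore no evidence about cell identity. Leaving out single libraries, between 2 and 8 tests passed, and 1 passed with peaks of −log10 q of 5 or more, with genes within 20 kb, and with any region within 50 kb.

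Genes of these 3 lists held more regions than other genes, with a median of 12 H3K27ac regions against 6 for the intestinal list, and 0 of the 102 tests passed when members were set against genes with a like number of regions, a comparison chosen after seeing the data. By those permutation draws, the intestinal list had 5.68 members by chance in place of 12 (adjusted p = 0.31) and the fibroblast and endothelial list 8.74 in place of 13 (adjusted p = 0.45). The TGF-beta and BMP list had 5.92 in place of 11 for MLL4 (permutation, adjusted p = 0.45) and 8.10 in place of 11 for H3K4me1 (adjusted p = 1).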

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

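Of the settings below, the gene matching, the H3K4me3 background, the H3K27ac pairs of 1 list each and MLL4 in any list were chosen after the results were seen. Over all settings, 139 values of the leading results counted as kept. These were counts within 1.5 times, differences in points of the same sign, and odds ratios on the same side of 1 and of the threshold. A kept sign can hide a large change, as for the MLL4 difference at tag sites, -7.36 points and -0.69 at equal list length. Of the other values, 40 counts moved by over 1.5 times or to 0, 5 passed only under the other setting, 6 no longer passed and 6 reversed. Where no construction is named, the cause was not tested. The 50% overlap moved no region count, since each peak lies wholly within its region. Depth is unknown and sets an unknown limit on absent peaks. The motif search was not run.

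With −log10 q of 5 or more, there were 1926 tag sites, 2061 control-only H3K27ac regions and 255 FOXD2-only MLL4 regions. The H3K27ac tag odds ratio reversed to 0.44, MLL4 in FOXD2-only against control-only H3K4me1 gave 7.00 and no longer passed, and the gene lists past the threshold were 1 for region classes and 0 for tag sites. With equal list lengths, which shorten the longer lists by construction, there were 13357 FOXD2-only H3K4me1 regions and 775 control-only MLL4 regions, the MLL4 tag odds ratio was 0.75 and MLL4 in H3K4me1 classes gave 5.81, neither past the threshold. With a gap of 500 bp the latter gave 8.79, also not past it. Tag sites numbered 18115 when both replicates of 1 tag sufficed and 13568 when 3 lists did, fewer lists being needed. With sites of at least 2 lists the H3K27ac tag odds ratio was 1.19 and passed. Gene lists past the threshold were 1 within 20 kb, 1 with any region within 50 kb and 0 when matched, and 0 for tag sites with the H3K4me3 background. MLL4 in any list reversed its odds ratio to 0.36. Control replicate 2 against FOXD2 replicate 1 gave 39134 FOXD2-only and 34326 control-only H3K27ac regions. Control replicate 1 against FOXD2 replicate 2 gave 57966 and 36884, with only 1 list to hold and 1 to lack a region.

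Leaving out each library in turn raises both classes of its mark. For its own group only 1 list must then hold a region, and for the other group only 1 list must lack it. The ranges were 6261 to 8578 tag sites, 24417 to 45308 FOXD2-only and 9336 to 16900 control-only H3K4me1 regions, 12698 to 50349 and 6498 to 32409 for H3K27ac, and 551 to 13999 and 3008 to 8339 for MLL4. Tag odds ratios ran from 1.28 to 2.10 for H3K4me1, 0.25 to 4.60 for H3K27ac, reversed without FOXD2 replicate 1, and 0.15 to 1.15 for MLL4, reversed at 1.15 and 1.03 without control replicate 1 and 2. MLL4 in H3K4me1 classes ran from 0.37, reversed without MLL4 FOXD2 replicate 2, to 51.7. The overlap of H3K27ac and H3K4me1 classes ran from 3.21 to 8.80, and gene lists past the threshold from 2 to 8.

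The labels give the groups the same replicate numbers. Over regions, the difference between the control replicates in holding a region was correlated with that between the FOXD2 replicates. These correlations were 0.01 for H3K4me1, -0.06 for H3K27ac and -0.03 for MLL4, so the numbers were not read as pairs. The labels give MLL4 a control and a FOXD2 input for each replicate number, so its libraries may still be paired. With the replicate block, a Mantel-Haenszel test over the replicate numbers, the tag odds ratios were 1.41, 1.43 and 0.46 for H3K4me1, H3K27ac and MLL4. By its p-values 3 of 3 passed in place of 2 of 3. Each FOXD2-only and control-only region was counted under both replicate numbers, so these p-values can be too small. The added call for H3K27ac is therefore no support. The block gave 3.45 for MLL4 in H3K4me1 classes and changed no other call.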

Other observations

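The patterns below were noticed in the peak lists first. The tests of their explanations were set out before their values were seen, and the choice of PCDH7 and of the gene lists named here came after.

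At PCDH7, H3K4me1 and H3K27ac covered less in FOXD2 cells, while H3K4me3 covered 1.7 kb against 0.7 kb in control (1 library each). The gene also held tag peaks, with 44.5 ± 20.5 for 6xHis and 28.5 ± 14.8 for FLAG (SD, n = 2) and 5 sites of all 4 lists. Of the other genes with the most control-only H3K4me1 regions, MPP7 had 7 such sites, PPP3CA 5, ZBTB20 3 and DCBLD2 2. Of those with the most FOXD2-only ones, FGGY and AKAP13 had 1 each and LPP, JARID2 and PRKCE 0, though LPP held 8.0 ± 4.2 tag peaks for 6xHis and 6.5 ± 0.7 for FLAG (SD, n = 2). Sites per gene do not say whether a site lies in a region of either class. Within the regions over the genome, tag sites lay in 0.83% of FOXD2-only and 0.44% of control-only H3K4me1 regions (odds ratio 1.90), the FOXD2-only ones being wider. Across VMP1, a membrane protein of autophagy with 14 tag sites, H3K4me1 covered 72.8 ± 1.2 kb in control and 52.1 ± 0.2 kb in FOXD2 lists (SD, n = 2). At the other 4 genes with the most tag sites, the FOXD2 lists covered more on average: 2.1 ± 1.2 and 6.1 ± 1.1 kb at MDM2, 14.8 ± 2.3 and 31.9 ± 3.4 kb at GBF1, 3.2 ± 1.1 and 10.3 ± 3.3 kb at MED13, and 15.3 ± 7.5 and 17.4 ± 4.0 kb at HNRNPC (SD, n = 2).

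Other gene lists showed no difference in H3K4me1, H3K27ac or MLL4 classes past the adjusted threshold. The nearest to it were forkhead genes with FOXD2-only H3K27ac at 16 of 28 members (57.1% against 29.1%, exact test, adjusted p = 0.053) and epithelial genes with control-only MLL4 at 9 of 20 (45.0% against 17.0%, exact test, adjusted p = 0.057). Among genes with a like number of regions, 13.03 and 6.49 members were expected (permutation draws, unadjusted p = 0.29 and 0.32). FOXD2-only H3K4me1 regions lay at 10 of 22 Wnt targets, as at AXIN2 and SOX9, 14 of 20 mesenchymal genes, as at ZEB1, and 17 of 28 forkhead genes, as at FOXQ1. They lay at 10 of 20 epithelial genes, 8 of 20 p53 targets, 7 of 21 cell cycle genes, 11 of 22 YAP and AP-1 targets, as at JUN, 8 of 19 Notch genes, 8 of 22 interferon and inflammatory genes and 6 of 17 members of H3K4 methyltransferase complexes. They lay at 5 of 30 HOX genes and 4 of 25 ribosomal protein genes, against 41.9% and 41.8% of other genes (Fisher's exact test, adjusted p = 0.071 and 0.09). Both lists had a median of 2 H3K4me1 regions per gene, against 5 for other genes. Among genes with a like number of regions, 6.8 HOX and 6.99 ribosomal members were expected (permutation draws, unadjusted p = 0.53 and 0.19). Control-only H3K4me1 regions also lay at 10 of 22 Wnt targets (45.5% against 21.5% of other genes, exact test, unadjusted p = 0.015, adjusted p = 0.12). Set against genes with a like number of regions, Wnt targets had 10 members in place of 7.03 for control-only and 10 in place of 14.32 for FOXD2-only H3K4me1 regions (permutation draws, adjusted p = 1 and 0.66).

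The H3K4me1 lists separated by group. List length does not account for this, since at equal length, regions of 1 group alone were 6.26 times as many as those of a control and a FOXD2 list (23050 against 3681). The groups are 2 stable lines, and a difference between the lines other than FOXD2, or between their histone inputs, 1 per group, may account for it, which was not tested. That FOXD2 changed H3K4me1 at these places remains a hypothesis.

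FOXD2-only H3K4me1 regions outnumbered control-only ones. Copy number differences were predicted to put the excess on few chromosomes. The FOXD2-only share was over 60% on 22 of 23, from 56.4% on chromosome 19 to 85.7% on X. X also had the highest share for H3K27ac, at 84.2%. Longer FOXD2 lists can raise the share on every chromosome, so this count does not exclude copy number differences of X or of single regions. Longer FOXD2 lists that reach weaker peaks stay open, since 17.0% of FOXD2-only regions had a peak in the better-ranked 50% of both FOXD2 lists, between the bounds set for either outcome, against 5.9% of control-only ones. Tagged FOXD2 at these regions could not be told apart from other sources either, since 13.6% held a peak of at least 1 tag list, against 8.1% of control-only ones and 34.8% of regions in all 4 lists. Their median widths were 935, 700 and 1855 bp, and wider regions hold more peaks by chance. An indirect effect of FOXD2 may also be at work and was not tested.

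H3K27ac regions of control replicate 1 and FOXD2 replicate 2 alone outnumbered those of either group. List length may account for this, since at equal length they were 0.69 times the FOXD2-only regions (5701 against 8275), though still more than the 5100 control-only ones. A swap of labels would tie the mixed regions to the H3K4me1 classes, but the odds ratio for overlap with those was 118 between the H3K27ac groups and 0.62 between the mixed classes. No biological explanation was tested, since the design gives none for this pair.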
